A study of Mus musculus with 4 samples.

How the data were processed

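RNA was measured in E14 cells, a line of mouse embryonic stem cells, on 4 one-colour Affymetrix arrays. Per the labels' protocols, the cells grew without feeders on gelatin in medium with 20% FBS, LIF, the MEK inhibitor PD0325901 at 1 µM and the GSK3 inhibitor CH99021 at 3 µM, a pair of inhibitors known as 2i. They carried a lentiviral shRNA against Usp22 or a Luc control shRNA. The labels gave 2 arrays for the control and 2 for Usp22 depletion, each group numbered 1 and 2. The titles and the treatment field set the groups. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

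The authors deposited 1 intensity per probe set and array on a linear scale, in a table of 28856 probe sets. Per the labels' protocols, total RNA was extracted with Trizol and column purification, and biotin-labelled cDNA was hybridised. The summarisation, background correction and normalization behind the deposited intensities are not given in the sources used here. Scanner files, scan dates and slide numbers were not used here. The lowest deposited intensity on every array lay at 16.0, and array medians ran from 110 to 128. The quartiles were 67.3 and 253 for control replicate 1, 72.2 and 247 for control replicate 2, 58.3 and 253 for depleted replicate 1, and 63.6 and 254 for depleted replicate 2. No pair of arrays held identical values (0 pairs).

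Because the values were linear, they were put on the log2 scale and quantile-normalized between the 4 arrays. The median of all genes was −0.12 on the log2 scale (depleted minus control) after this step, −0.24 on the deposited values put on the log2 scale alone, and −0.09 after centring each array on its median. Log2 fold changes are given as fitted and were not shifted by this median. Probe sets were named through GEO's annotation of the platform, which can be old. It gave 1 symbol to 21789 probe sets and several to 1621, and 5446 were not named here. Of the probe sets with 1 symbol, 21698 matched the mouse RefSeq table (assembly GRCm38.p6) through the gene ID, and 0 symbols changed. The files name no genome build, so no coordinates are given. The brightest probe set by mean over the 4 arrays was kept for each of 999 genes with several, which left 19938 genes. Different probe sets of a gene were averaged as an alternative.

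Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a model of 2 groups, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes). Adjusted p-values without another tool beside them come from this fit. The fit had 2 residual degrees of freedom, and its prior degrees of freedom were infinite. All genes therefore shared a standard error of 0.27 on the log2 scale, and the smallest called change was 0.86 in size. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333. Genes whose 2 arrays of one group both lay beyond both arrays of the other are described as without overlap, and those with a fold of at least 1.5 were counted. The number of arrays limits the precision of every value. Signals near the floor of the array were judged against 1194 olfactory and vomeronasal receptor genes. The 95th percentile of their mean signals, 6.99 on the log2 scale, is called the receptor background. A gene is called above it by its mean over the 4 arrays, unless the brighter group's mean is named.

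Before the data were examined, the comparison, the tests, 28 gene lists, the rule for named genes and the alternative settings were fixed. The rule named Usp22, Sox2, Pou5f1 and Nanog always, the 12 called genes without overlap with the largest change in each direction, and up to 4 members of each list with the lowest p. Genes without an official symbol and olfactory and vomeronasal receptors were counted but left out of the 12. The 27 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. Camera with an estimated correlation, camera on ranks and fry were alternatives. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit. It can hardly pass any list here, so a list that it does not pass stays undecided.

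The tests were run on simulated data first. Among 19938 simulated genes, limma recovered 0 of 50 genes changed 1.5-fold, 2 of 50 changed 2-fold, 43 of 50 changed 3-fold and 50 of 50 changed 4-fold. It made 1 false call among 19738 unchanged genes, and 0 lists were called where no gene was changed. The simulated noise was independent between genes and equal in both groups. On the arrays, deviations from the group mean had an SD of 0.23 for control and 0.14 for depleted. The simulation therefore does not give the rate of false calls for these data. The other alternatives were the replicate number as a block, other scaling, filters on dim genes, limma's eBayes with an intensity trend and robust settings, an unmoderated statistic, all probe sets, other thresholds and leaving out each array in turn. Where an array is left out, the lone array of its group is assumed to vary like the other group. The deposited values on the log2 scale alone, a filter at the receptor background, the intensity trend and the robust settings each on its own, and other scaling without control replicate 2 were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.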

Results

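Gene expression was compared between E14 mouse embryonic stem cells depleted of Usp22 by shRNA and cells carrying a Luc control shRNA, with 2 arrays in each group. Usp22 is the deubiquitinating enzyme of SAGA, a transcriptional coactivator complex that also carries a histone acetyltransferase. All cells were kept in 2i and LIF, which hold stem cells in the naive state. The comparison asks which genes differ in signal when Usp22 is reduced under these conditions. Across 19938 genes, the Pearson correlation of normalized log2 signal between the depleted arrays was 0.978, and that between the control arrays was 0.941. Control replicate 1 correlated at 0.951 and 0.974 with the depleted arrays, and control replicate 2 at 0.877 and 0.908. These are correlations across genes, which are not independent replicates. On the first principal component, which held 75.1% of the variance, control replicate 2 lay at −55.5, control replicate 1 at −3.30, and the depleted arrays at 37.0 and 21.9.

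Usp22 signal was lower on both depleted arrays. Its log2 signal was 9.41 and 9.36 on the control arrays and 8.23 and 8.29 on the depleted arrays, or 9.38 ± 0.039 against 8.26 ± 0.044 (SD, n = 2 each). The fall was 2.17-fold (log2 fold change −1.12, standard error 0.27, limma adjusted p = 0.00826). Leaving out 1 array at a time moved the value between −1.15 and −1.09. The call ended without either depleted array, where the limma adjusted p was 0.830 without replicate 1 and 0.360 without replicate 2.

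The central pluripotency factors did not pass the test. Sox2 was higher by its group means (log2 fold change 0.59, limma adjusted p = 0.182), and its signal was 9.20 ± 0.23 in controls and 9.79 ± 0.15 in depleted cells (SD, n = 2 each). Pou5f1 (Oct4) had a log2 fold change of −0.31 (limma adjusted p = 0.422) and Nanog one of −0.42 (limma adjusted p = 0.308), both lower on each depleted array than on each control array. With limma's intensity trend and robust settings, Sox2 and Nanog passed the threshold (adjusted p = 0.0120 and 0.00257). They also passed with the trend alone (limma adjusted p = 0.0175 and 0.000102), but not with the robust settings alone (0.219 and 0.342). The scaling moved these values too. With each array centred on its median, Nanog stood at −0.17, Pou5f1 at −0.08 and Sox2 at 0.80 (limma adjusted p = 0.651, 0.835 and 0.0548). Sox2 also passed without control replicate 1, at a log2 fold change of 0.75 (limma adjusted p = 0.00945), against 0.43 without control replicate 2.

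**Figure D1:**
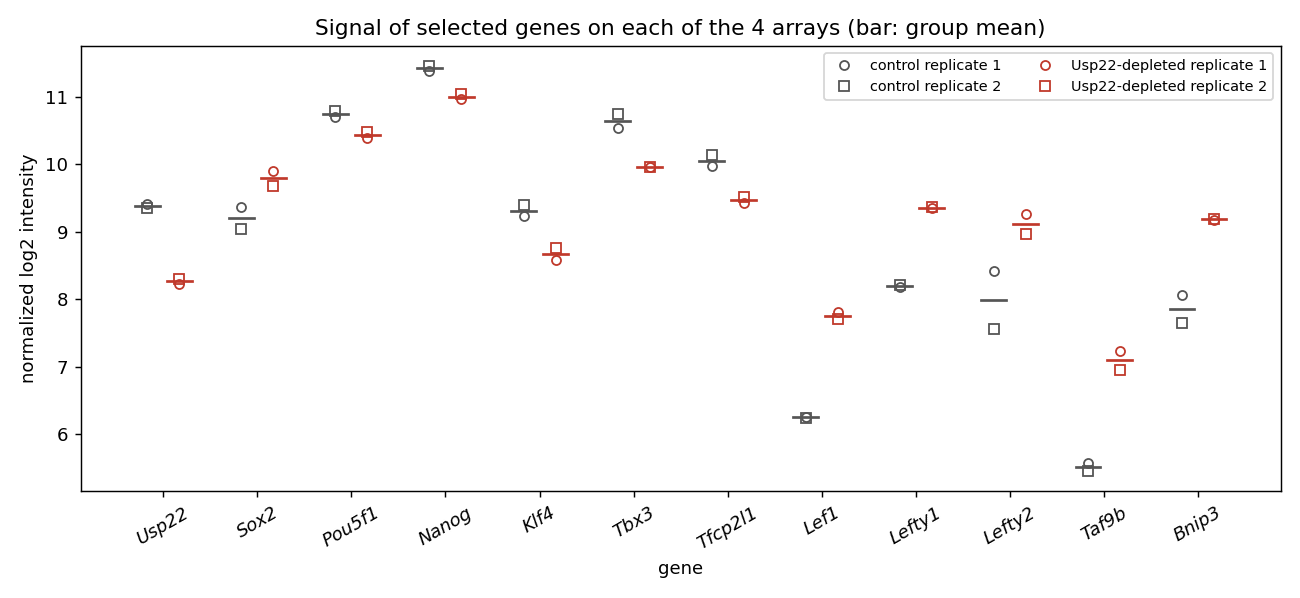
Normalized log2 intensity of 12 named genes on each of the 4 arrays; circles are replicate 1, squares are replicate 2, grey is control, red is Usp22-depleted and bars are group means. Usp22 lies at 8.23 and 8.29 on the depleted arrays and at 9.41 and 9.36 on the controls, while Lef1 and Lefty1 lie higher on both depleted arrays.

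Among the genes with the largest increases were Taf9b, a TAF9 paralog counted here with SAGA, at 3.01-fold (5.51 ± 0.079 to 7.10 ± 0.20 on the log2 scale, SD, n = 2 each), the organic anion transporter gene Slco4c1 at 2.95-fold, the Ras exchange factor gene Rasgrp3 at 2.88-fold and Lef1, a transcription factor of the Wnt pathway, at 2.84-fold (limma adjusted p from 6.04e-05 to 9.39e-05). Further genes among the 12 with the largest increases were the peptide transporter gene Slc15a2 at 2.72-fold, the receptor tyrosine kinase gene Met and the proteoglycan gene Srgn, both at 2.69-fold, the fatty acid binding protein gene Fabp6 and the lens crystallin gene Crygd, both at 2.62-fold, Gtsf1, a factor of the germline piRNA pathway, at 2.57-fold, the R-spondin receptor gene Lgr4 at 2.55-fold and the muscle gene Neb at 2.53-fold (limma adjusted p up to 0.000828). Of these 12, only Lef1 and Lgr4 were above the receptor background by their mean over the 4 arrays, and Rasgrp3, Slc15a2, Met and Fabp6 were under it in both groups' means. Without control replicate 2, the log2 fold change of Met moved from 1.43 to 0.80 and its call was lost, while the other 11 kept theirs. None of the 12 passed without either depleted array.

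Beside Usp22, the genes with the largest decreases included Angpt1, which encodes a ligand of the Tie2 receptor (log2 fold change −1.48), Mat1a, which encodes a methionine adenosyltransferase (−1.13), AI182371 (−1.11), the antimicrobial peptide gene Camp (−1.08), C2cd4b (−1.08) and Ncr1, a receptor gene of natural killer cells (−0.99). The cytokine gene Il33 (−0.99), the imprinted gene Rtl1 (−0.94), the BMP-family gene Gdf6 (−0.93), Nxf2, a member of the RNA export factor family (−0.92), and the glutamate transporter gene Slc1a2 (−0.87) completed the 12 (limma adjusted p from 0.000137 to 0.0470). AI182371 and Ncr1 were under the receptor background in both groups' means, and Mat1a by its mean over the 4 arrays. Several of these rested on 1 array. Angpt1 read 10.3 on control replicate 2 and 7.74 on control replicate 1, against 7.52 and 7.60 on the depleted arrays, so that its log2 fold change was −0.19 without control replicate 2. Il33 and Nxf2 moved to −0.14 and −0.15 without that array, Gdf6 to −0.43, Slc1a2 to −0.53, Ncr1 to −0.63 and C2cd4b to −0.65. Mat1a read 4.88 on depleted replicate 1 and 7.06 on depleted replicate 2, and without depleted replicate 1 its log2 fold change was −0.04. Without depleted replicate 1, that of Gdf6 was −0.54. Without control replicate 2, of the 12 only Usp22 passed, and of the 12 only Mat1a passed without depleted replicate 2 (−2.23).

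In all, 523 genes rose and 21 fell (limma adjusted p under 0.05), of which 523 and 20 were without overlap. At an unadjusted p under 0.05, 3078 genes were higher and 1322 lower. Above the receptor background lay 176 of the genes that rose and 16 of those that fell by the mean over the 4 arrays, and 323 and 17 by the mean of the brighter group. A fold of at least 1.5 without overlap was seen for 2418 genes in the higher and 667 in the lower direction. Genes without overlap at any fold made up 60.7% of all genes. Chance gives 33.3% for 1 gene taken alone. Genes moved together over the 4 arrays, with 75.1% of the variance on the first principal component, so the gap does not measure an excess over chance. The higher share of the 1.5-fold genes was 78.4% here, 91.6% with each array centred on its median and 51.2% on the deposited log2 values. With limma's intensity trend and robust settings, 381 genes rose and 339 fell, of which 220 and 15 were among those called above. The trend alone gave 326 and 286, and the robust settings alone gave 295 and 11. The counts followed single arrays: 4884 genes rose and 4236 fell without control replicate 1, 66 and 2 without control replicate 2, 0 and 0 without depleted replicate 1, and 0 and 1 without depleted replicate 2 (limma). At an unadjusted p under 0.05, the counts were 540 higher and 48 lower without depleted replicate 1, and 1628 and 338 without depleted replicate 2. Of 51 named genes that passed the test, 17 passed without control replicate 2, 0 without depleted replicate 1 and 1 without depleted replicate 2, and all 51 kept their sign each time. The 17 were Usp22, the 12 genes with the largest increases except Met, and Bnip3, Egln3, Lefty1, Sox11 and Usp29. Genes without overlap keep their sign by construction when 1 array is left out, so the kept signs are no test.

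**Figure D2:**
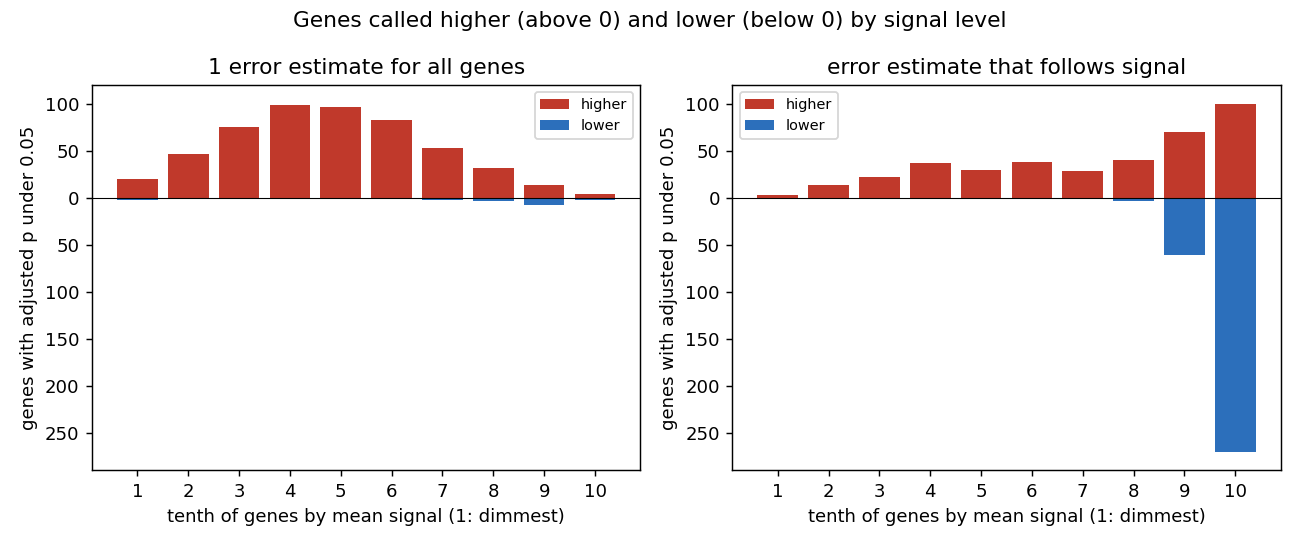
Number of genes called higher (above 0, red) and lower (below 0, blue) with adjusted p under 0.05 in 10 groups of genes of equal size by mean signal, from 1 (dimmest) to 10, for the shared error estimate on the left and the intensity trend with robust settings on the right. In the brightest group, 4 genes were called higher and 2 lower on the left, and 100 and 271 on the right.

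Genes of glycolysis and the hypoxia response stood higher as a group. Of 26 measured members, 5 rose (6 adjusted over the list alone) and 0 fell, and the median log2 fold change was 0.48. Those that rose were the mitophagy receptor gene Bnip3 (log2 fold change 1.33), the oxygen-sensing prolyl hydroxylase gene Egln3 (1.19), Ankrd37 (1.05), the aldolase gene Aldoc (0.98) and, named after its value was seen, the collagen prolyl hydroxylase gene P4ha1 (0.96). The adjusted p was 0.000111 by camera with the preset correlation, and 0.887 with an estimated correlation. Of 18 measured genes of cholesterol biosynthesis, 3 rose (8 adjusted over the list alone) and 0 fell, with a median of 0.59. Cyp51 (0.94), Lss (0.92) and Idi1 (0.86), which encode enzymes of the sterol pathway, passed the test, while Insig1, a regulator of that pathway, stood at 0.82 (limma adjusted p = 0.0654). The camera adjusted p was also 0.000111 (0.887 with an estimated correlation). Without control replicate 2, the median moved to 0.40 for the glycolysis and hypoxia list and to 0.42 for the cholesterol list, and Lss moved to 0.41.

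Genes of the formative and primed epiblast, the states that follow naive pluripotency, were higher as a group. Of 24 measured, 4 rose (10 adjusted over the list alone) and 0 fell, with a median of 0.40. Without overlap, 13 members were higher and 4 lower. Those that rose were Lef1 (1.51), the Nodal antagonist genes Lefty1 (1.17) and Lefty2 (1.13), and the carbonic anhydrase gene Car4 (0.94). The 4 lower members, named after their values were seen, were Sox3 (−0.46, and −0.20 without control replicate 2), Pou3f1 (−0.40), Etv4 (−0.30) and the growth factor gene Fgf5 (−0.28, and −0.14 without control replicate 1), none of which passed the test. The camera adjusted p was 0.00632 (0.887 with an estimated correlation). Lefty2 and Car4 moved to 0.70 and 0.62 without control replicate 2, while Lefty1 kept 1.18. Among 22 measured naive pluripotency genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with members on both sides of 0. Pecam1 stood at 0.69, and the naive transcription factor genes Tbx3, Klf4 and Tfcp2l1 stood at −0.67, −0.64 and −0.58. The list did not pass (camera adjusted p = 0.878). With limma's intensity trend and robust settings, Tbx3 (adjusted p = 2.91e-05), Klf4 (0.0215) and Tfcp2l1 (0.00613) fell. With each array centred on its median, these 3 stood at −0.43, −0.42 and −0.37. The core pluripotency list held 23 measured genes, of which 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Rif1 at 0.59, Zfp281 at 0.52 and Dppa2 at 0.48 (camera adjusted p = 0.878). Rif1 and Dppa2 stood at 0.34 and 0.30 without control replicate 2.

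Genes of G2/M, p53 targets and replication-dependent histone genes were also higher as groups. Of 26 measured G2/M genes, 1 rose, the spindle gene Nusap1 (0.87), or 2 adjusted over the list alone, and 0 fell. The median was 0.35, with the kinesin gene Cenpe at 0.78, Hmmr at 0.72 and the checkpoint kinase gene Ttk at 0.63, and 20 members were higher without overlap against 0 lower. Without control replicate 2 the median was 0.23, with Hmmr at 0.45 and Ttk at 0.36. The camera adjusted p was 0.00247 (0.887 with an estimated correlation). Of 25 measured p53 targets, 1 rose, the BH3-only gene Pmaip1 (1.04), or 5 adjusted over the list alone, and 0 fell. Their median was 0.32, with Sesn1 at 0.83, Eda2r at 0.76 and Cd80 at 0.75, and it was 0.21 without control replicate 2 and 0.60 without control replicate 1. The camera adjusted p was 0.0193 (0.893 with an estimated correlation), and the call was lost without control replicate 2 (adjusted p = 0.188). Replication-dependent histone genes had a median of 0.31, with 1 of 27 higher, the testis linker histone gene H1f6 (0.89; 1 adjusted over the list alone), and 0 lower. The camera adjusted p was 0.0193 (0.887 with an estimated correlation), and it was 0.0853 without control replicate 1 and 0.0843 without depleted replicate 1. With the dimmer 0.5 of genes left out, camera called neither the p53 list (adjusted p = 0.150) nor the histone list (0.214). The histone call was also lost with the dimmest 0.25 of genes left out (camera adjusted p = 0.166), above the receptor background (0.211) and with a trended variance (0.0571), and the p53 call above the receptor background (0.148). In the G1/S list, 1 of 25 rose (1 adjusted over the list alone) and 0 fell. The gene was Ccne2, encoding a cyclin E (0.90, and 0.46 without control replicate 2), and the camera adjusted p was 0.307. With each array centred on its median and on the deposited log2 values, the G1/S list passed (camera adjusted p = 0.0204 in both). In the fit used here its adjusted p was 0.911 with an estimated correlation and 0.956 without control replicate 2, where its median was 0.02.

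Hox genes, the homeobox genes of the body axis, were lower as a group (median −0.32), although 0 of 37 measured genes rose or fell singly (0 and 0 adjusted over the list alone). Hoxa4, Hoxc8 and Hoxa5 stood at −0.72, −0.69 and −0.55, and Hoxc13 at 0.77. Hoxa4, Hoxc8 and Hoxc13 stood at −0.42, −0.45 and 0.41 without control replicate 2. By the mean of the brighter group, 12 of the 37 lay above the receptor background. The camera adjusted p was 0.00642 (0.887 with an estimated correlation) and 0.173 without control replicate 2, where the median was −0.12, against −0.52 without control replicate 1. The 1194 receptor genes had a median of −0.20, or −0.05 without that array. Of the 7 lists called by camera, none held with an estimated correlation. The estimates for these lists ran from 0.050 (formative and primed epiblast) to 0.53 (G2/M), all above the preset 0.01. For the glycolysis and hypoxia list the estimate was 0.28, and for the cholesterol list 0.21. With 2 residual degrees of freedom camera also has little power, and the 2 reasons for the lost calls were not told apart. The endoderm list, with an estimated correlation of 0.00049, moved from an unadjusted camera p of 0.244 to 0.326. The lowest adjusted p by fry, which asks whether a list's genes move one way, was 0.292.

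**Figure D3:**
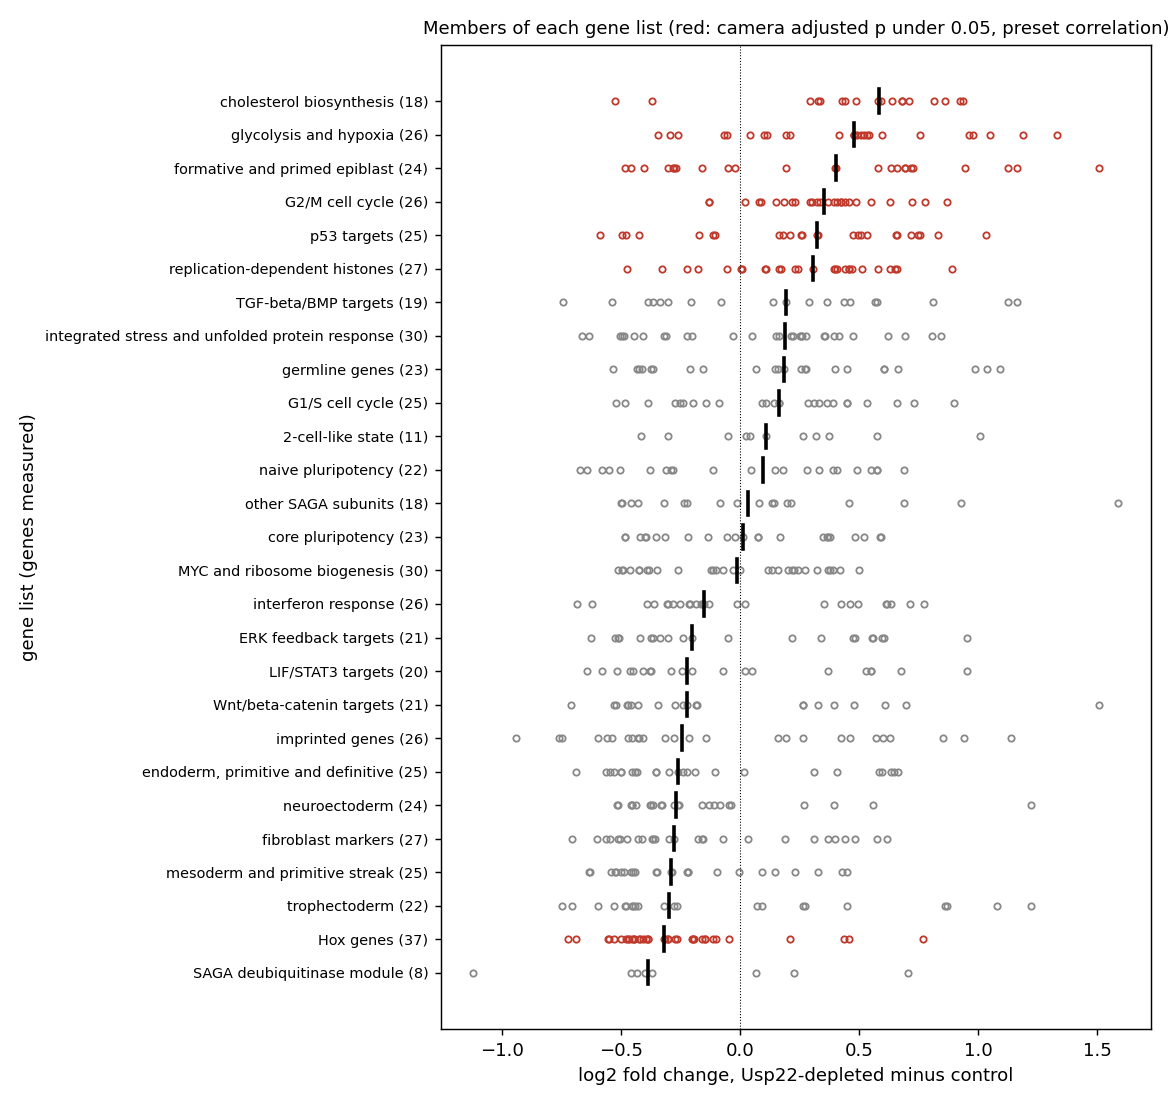
Log2 fold change (depleted minus control) of every measured member of the 27 tested gene lists, with 1 circle per gene and a black bar at the list's median. Lists drawn in red passed the camera test at the preset correlation, with medians from 0.31 to 0.59 for the 6 higher lists and −0.32 for the Hox genes.

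The SAGA deubiquitinase module list also counted Usp51 and Usp27x, genes of related enzymes. Of its 8 measured genes 1 fell, Usp22, and 0 rose (1 and 1 adjusted over the list alone). Usp51, a related deubiquitinase gene, stood at 0.70 (limma adjusted p = 0.113), and the cofactor genes Atxn7l2 and Atxn7l3 stood at −0.46 (−0.18 without control replicate 2, −0.73 without control replicate 1) and −0.43 (camera adjusted p for the list = 0.307). Of 18 other SAGA subunit genes, 2 rose (2 adjusted over the list alone) and 0 fell. These were Taf9b and the acetyltransferase gene Kat2b (0.93, and 0.59 without control replicate 2). Taf9, the paralog of Taf9b, stood at 0.69 (limma adjusted p = 0.122), and the list as a whole did not pass (camera adjusted p = 0.626).

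In the trophectoderm and neuroectoderm lists single genes rose, and neither list passed. Of 22 measured trophectoderm genes, 4 rose and 0 fell (4 and 2 adjusted over the list alone). They were the growth factor receptor gene Fgfr2 (1.22), Plet1 (1.08) and the transcription factor genes Ets2 (0.87) and Tfap2a (0.86), the last pair moving to 0.36 and 0.40 without control replicate 2. The median of that list was −0.30, and −0.16 without control replicate 2 (camera adjusted p = 0.875). In the neuroectoderm list, 1 of 24 rose, Sox11 (1.22; 1 adjusted over the list alone), and 0 fell, with Pax6 at −0.51 (camera adjusted p = 0.307). Of 25 measured mesoderm and primitive streak genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Gata2, Evx1 and Isl1 at −0.63 (−0.40 without control replicate 2), −0.63 and −0.54 and a median of −0.29 (−0.16 without control replicate 2 and −0.52 without control replicate 1). This list missed the threshold (camera adjusted p = 0.0712, and 0.887 with an estimated correlation). It passed as lower with each array centred on its median and on the deposited log2 values (camera adjusted p = 0.0438 in both), with the dimmest 0.25 (0.0450) or dimmer 0.5 (0.0247) of genes left out, above the receptor background (0.0247) and on ranks (0.0474). All of these settings kept control replicate 2. In control replicate 1 minus control replicate 2, the list's median was −0.35, so its genes differed between the controls as well. Of 25 endoderm genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Amn at −0.69 and Lama1 at 0.66, or 0.40 without control replicate 2 (camera adjusted p = 0.412). Markers of fibroblasts, included as another cell type that a culture could hold, had a median of −0.28, with Col1a1 at −0.60 (−0.24 without control replicate 2, −0.96 without control replicate 1) and Timp3 at 0.62. Of 27 measured, 0 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.307).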

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

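The deposited values on the log2 scale alone, the filter at the receptor background, the intensity trend and robust settings each on its own, and other scaling without control replicate 2 were chosen only after the result was seen; all other settings were planned. Quantile normalization on top of the deposited values was planned and is what the results above use, so it gave no further value. The sign of all 51 named genes that passed the test held in every setting in which single genes were followed. Where 1 array is left out this holds by construction, since these genes were without overlap. Other error estimates and filters leave fold changes as they are. Only the other scalings and the mean of all probe sets could turn a sign. The 51 had been called with changes of at least 0.86 in size, and centring moved Usp22 only from −1.12 to −0.92. The kept signs are therefore a weak test there too. The calls of the 51 did not hold. With limma's intensity trend and robust settings 37 passed, with the trend alone 39 and with the robust settings alone 38. On the deposited log2 values 27 passed, and with the unmoderated statistic 0 did. Above the floor of the array, signal limits the dimmer genes, where most calls lay: 338 of the 523 higher calls were among the dimmer 0.5 of genes by mean signal. Where no cause is named, the cause was not tested.

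With the replicate number as a block, limma called 856 genes higher and 42 lower, which included the 523 and 21 called without it, and 6 lists higher and 1 lower. Deviations of same-numbered arrays from their group means correlated at 0.105 across genes. With 2 pairs, this cannot tell whether same-numbered arrays share more than a number. With each array centred on its median, 927 genes were called higher, 321 genes had a fold of at least 1.5 without overlap in the lower direction, and 2 lists were called lower. On the deposited log2 values, 75 genes were called higher and 10 lower, 1654 genes had such a fold in the lower direction, and 2 lists were lower. Leaving out the dimmest 0.25 of genes gave 36 genes and 2 lists lower. Leaving out the dimmer 0.5 of genes gave 148 lower calls, 1213 genes with a fold of at least 1.5 without overlap in the higher direction and 2 lists lower. The filter at the receptor background gave 149, 1163 and 2. These filters test fewer genes by construction. With limma's intensity trend and robust settings, 339 genes were called lower, and Nanog (log2 fold change −0.42) and Sox2 (0.59) passed the threshold. The trend alone gave 326 genes higher and 286 lower, with Nanog and Sox2 past the threshold at the same −0.42 and 0.59, and the robust settings alone gave 295 and 11. The unmoderated statistic called 1 gene higher and 0 lower, with 2032 genes at an unadjusted p under 0.05, and Usp22 at −1.12 did not pass (adjusted p = 0.472). All probe sets tested singly gave 32 lower calls. At an adjusted p under 0.10, 1144 genes were higher and 86 lower; limma's treat against a fold of 1.2 gave 14 and 2; an unadjusted p under 0.01 with a fold of at least 1.5 gave 1487 and 163. A fold of at least 2 without overlap held for 159 genes in the higher and 7 in the lower direction. Camera with an estimated correlation called 0 lists higher and 0 lower, fry also called 0 and 0, and camera on ranks called 2 lists lower.

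Leaving out 1 array at a time, limma calls ran from 0 (without depleted replicate 1) to 4884 higher and from 0 to 4236 lower (without control replicate 1). Genes with a fold of at least 1.5 without overlap ran from 968 (without control replicate 2) to 4472 higher and from 278 to 3402 lower (without control replicate 1), all on quantile-normalized values. With control replicate 2 left out, 53 genes were called higher and 2 lower with the arrays centred on their medians, where 1259 and 250 had such a fold, and 24 and 4 on the deposited log2 values, where 610 and 707 did. Lists called lower ran from 0 without control replicate 2 to 1. Sox2 ran from 0.43 to 0.75 and passed without control replicate 1. Usp22 ran from −1.15 to −1.09 and did not pass without either depleted array, where limma's shared error rises because it then comes from the control arrays alone.

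Lists that passed in none of these settings turned direction near 0, by the mean or by camera's direction alone. Their mean log2 fold change minus that of other genes is given for each. With each array centred on its median, and alike on the deposited log2 values, imprinted genes stood at 0.017, the MYC and ribosome biogenesis list at 0.13 and the interferon list at −0.022. Without the dimmest 0.25 of genes, ERK feedback targets stood at −0.014 and Wnt targets at 0.011. Without the dimmer 0.5 of genes, naive pluripotency stood at −0.00071, ERK feedback targets at −0.042 and the stress and unfolded protein response list at −0.0064. Above the receptor background, ERK feedback targets stood at −0.042 and the stress list at −0.0060. With a trended variance, camera's direction turned for core pluripotency (0.031), naive pluripotency (0.016) and ERK feedback targets (0.016), and on ranks for ERK feedback targets (0.016). With the mean of all probe sets of a gene, ERK feedback targets stood at −0.0035. Over the settings without 1 array, the ranges were 0.0057 to 0.18 for other SAGA subunits, where only camera's direction turned (without control replicate 2), −0.055 to 0.12 for core pluripotency, −0.0039 to 0.035 for naive pluripotency, −0.093 to 0.049 for MYC and ribosome biogenesis, −0.025 to 0.080 for interferon, −0.043 to 0.075 for ERK feedback targets, −0.055 to 0.0097 for Wnt targets and −0.093 to 0.0016 for LIF/STAT3 targets. The mitochondrial gene COX2 ran from −0.00073 to 0.27.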

Other observations

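The tests of control replicate 2 by the share of higher calls and of a shared error estimate for the excess of higher calls were chosen only after the result was seen, as were the values on the deposited log2 scale and the counts of genes by size of the difference.

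Germline genes held 3 of 23 measured members that rose and 0 that fell (3 and 0 adjusted over the list alone). They were the synaptonemal complex gene Sycp3 (log2 fold change 1.09), the piRNA pathway gene Mael (1.04) and the meiotic cohesin gene Smc1b (0.99), with Rhox13 at 0.66, and the list did not pass (camera adjusted p = 0.175). Of 26 measured imprinted genes, 2 rose, Usp29 (1.14) and Mkrn3 (0.94), and 1 fell, Rtl1 (−0.94), against 3 and 3 adjusted over the list alone. Grb10 stood at 0.85 (limma adjusted p = 0.0517), and the list did not pass (camera adjusted p = 0.875). Of 11 measured genes of the 2-cell-like state, 1 rose, Tdpoz3 (1.01; 1 adjusted over the list alone), and 0 fell (camera adjusted p = 0.346). Of the genes that passed here, only Usp29 passed without control replicate 2 (1.04), where Sycp3, Mael and Smc1b stood at 0.82, 0.80 and 0.73, Mkrn3 at 0.84, Rtl1 at −0.89 and Tdpoz3 at 0.86.

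Among signalling lists, none passed camera. Of 21 ERK feedback targets, 1 rose, the immediate early gene Ier3 (0.95; 1 adjusted over the list alone), and 0 fell, with Egr1 at −0.62 (−0.28 without control replicate 2, −0.97 without control replicate 1); the list's median was −0.20 (−0.10 without control replicate 1) while its mean was 0.02 (camera adjusted p = 0.878). Ier3 was also the only 1 of 20 LIF/STAT3 targets to rise (1 adjusted over the list alone; camera adjusted p = 0.875), and Lef1 the only 1 of 21 Wnt targets (1 adjusted over the list alone; 0.878), with Fgf18 at −0.71 (−0.38 without control replicate 2). Of 19 TGF-beta and BMP targets, Lefty1 and Lefty2 rose and 0 fell (3 and 1 adjusted over the list alone; 0.307). Of 26 interferon response genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone; 0.878), with Ddx58 at 0.77 and Irf9 at −0.68 (−0.44 without control replicate 2), a median of −0.15 (0.0017 without control replicate 1) and a mean of 0.03. Of 30 MYC and ribosome biogenesis genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone; 0.878), with Polr1a at −0.51 and Nop58 at 0.50 (0.33 without control replicate 2). Of 30 genes of the integrated stress and unfolded protein response, 0 rose and 0 fell (2 and 0 adjusted over the list alone; 0.646), with Stc2 at 0.84 and Chac1 at −0.66 (−0.35 without control replicate 2). Of the mitochondrially encoded genes only 2 were measured, ND3 at 0.32 (0.12 without depleted replicate 1, 0.52 without depleted replicate 2) and COX2 at 0.14, and the list was not tested.

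Log2 differences between the groups fell into 2 broad sets of genes with a dip between them. From −0.5 to −0.3 lay 4586 genes, from −0.1 to 0.1 lay 2172, from 0.1 to 0.3 lay 1935 and from 0.3 to 0.5 lay 2218. Without control replicate 2, the counts in these ranges were 3543, 3779, 3152 and 2364. For depleted replicate 2 minus depleted replicate 1, they were 1678, 5915, 4965 and 1994, and for control replicate 2 minus control replicate 1 they were 2684, 2607, 2704 and 2905. Probe sets without a single gene name numbered 7067, of which 165 were called higher and 9 lower in a limma fit of all probe sets.

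The excess of higher calls, 523 against 21, was weighed against control replicate 2, the scaling and the error estimate. With control replicate 2 left out, the lowest share of higher calls over the quantile-normalized, median-centred and deposited values was 85.7%. This share cannot decide about that array. Most calls were lost without it, and those left were made with the shared error estimate. Without quantile normalization 88.2% of the calls were higher on the deposited log2 values and 97.9% with each array centred on its median. Calls made with the shared error estimate were thus uneven without that step too. Few calls were left on the deposited values, and all rest on that error estimate, so this share does not settle what the step adds. The share among genes with a fold of at least 1.5 and no overlap, the test first set for control replicate 2, decides neither: without that array it was 77.7%, but 46.3% on the deposited values and 83.4% after centring, and with all arrays 51.2% (where 75 genes were called higher and 10 lower) and 91.6%, settings that differ by 1 offset for all genes. Without control replicate 1, 56.8% of the genes with such a fold and no overlap were higher. With the intensity trend alone 53.3% of the calls were higher, and with the robust settings alone 96.4%. With both, the brightest of 10 groups by signal held 100 higher and 271 lower calls. Dimmer groups stayed uneven, as the 4th did with 37 higher and 1 lower, against 99 and 1 with the shared error. The trend was fitted on quantile-normalized values only. A single error estimate shared by bright and dim genes is thus a candidate explanation for the share over all genes only. It leaves the uneven calls among dimmer genes unexplained, and an effect of Usp22 depletion was not tested.

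The higher glycolysis and hypoxia list and the higher cholesterol list were weighed against signal level and the difference between the control arrays. For each list, 10000 random lists were matched on mean signal and on control replicate 1 minus control replicate 2, and the median of depleted minus control replicate 1 was compared. Both lists lay at percentile 100 of their random lists, with medians of 0.40 and 0.42. Genes drawn singly with like signal and control difference thus did not give such medians. The random lists hold no movement shared between genes, whereas the estimated correlations within these lists were 0.28 and 0.21. The comparison also rests on 1 control array. The percentiles therefore cannot exclude a movement shared by the genes of a list. Medium, cell density and handling of the cultures were not tested and stay open, as does an effect of Usp22 depletion. The lists' calls were lost with an estimated correlation, which has too few degrees of freedom here to decide.

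The lower Hox list was weighed in the same way. Its median of depleted minus control replicate 1, −0.12, lay at percentile 29.5 of the matched random lists, whose median was −0.09. The low Hox signal may therefore come from signal level and the difference between the control arrays, since the Hox genes stood −0.40 by median in control replicate 1 minus control replicate 2. Among the other lists called higher, p53 targets lay at percentile 87.2, where the same explanation stays open, G2/M at 98.05, replication-dependent histones at 99.3 and the formative and primed list at 99.7. These percentiles too come from random lists without movement shared between genes. An effect of Usp22 depletion on the Hox genes and on these lists stays open, as untested.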
